A study of Mus musculus with 12 samples.

How the data were processed

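Kidney inner medulla RNA of 3 wild-type (WT) and 3 aquaporin-1 knockout (KO) mice was compared on 12 two-channel microarrays. Per the labels, each array carried RNA of 1 mouse in each channel, and each of the 6 mice lay on 4 arrays, 2 times in channel 1 and 2 times in channel 2. Of the arrays, 3 paired WT mice with each other, 3 paired KO mice with each other, and 6 paired a WT with a KO mouse, 3 in each channel order. WT and KO mice that bear the same number were never on the same array. The labels call the mice by genotype and number, so the mouse was the replicate (n = 3 per genotype).

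The deposited table holds 1 signed log ratio per probe and array, for 15600 probes and 12 arrays, and is treated here as log2. No value was missing and none was exactly 0, the values ran from -7.01 to 9.97, and no array columns were identical. The deposited medians of the 12 arrays lay between -0.047 and 0.040. The log base was not given in the sources used here. A base of 10 is excluded if the ratios came from 16-bit intensities, because the highest value would exceed the base-10 logarithm of the largest intensity (4.82), but a natural logarithm is not excluded. Scanner, dyes, background correction, normalization, spot filters and centring are likewise not given in the sources used here. Raw intensities and spot flags were not analysed here, so signal over background is unknown and the number of arrays is what is known to limit precision.

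The direction of the ratio (channel 1 over channel 2 or the reverse) is not stated in the labels or the table. Values are computed as if channel 1 were the numerator on every array. If the convention was the reverse on every array, every sign turns and no size, test or count changes. For this reason no probe is called higher or lower in either genotype, and differences are given as sizes on 2 opposite sides. The rule fixed before the data were examined would have settled the direction from the deleted gene, Aqp1, but the table carries only probe IDs. None (0) of the IDs matched a symbol, synonym or locus tag in the RefSeq gene table used here, which belongs to the GRCm38.p6 assembly. Genes are therefore not named, and the planned Aqp1 check and the tests of gene lists and cell type markers were not run. The IDs comprise 15264 with the prefix H3 and 336 with the prefix Z3. Their first 5 characters form 163 blocks, which are read here as source plates.

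The median of each array was subtracted. For each probe, the 12 log ratios were fitted by least squares with a value for each mouse, relative to the mean of the 6 mice, and a channel term, which leaves 6 residual degrees of freedom. The 6 mouse values were compared between genotypes with limma (lmFit and eBayes) and p-values were adjusted by the Benjamini-Hochberg method. Because of the balanced loop, the KO-WT estimate of a probe equals the mean of the 6 WT-KO arrays, and the other 6 arrays enter through the error alone. The technical variance of a KO-WT difference is 1.2 times what the spread of mouse values within genotypes carries, so this test is slightly liberal for probes in which technical error dominates. For differences between single mice, limma was fitted to the 12 arrays with the mice as fixed terms. That fit tests whether RNA samples differ beyond array error, not whether genotypes differ. Each array was also predicted from a fit to the other 11, and the Pearson correlation across probes of measured and predicted ratios was given with a 95% bootstrap interval over source plates (1000 draws). Probes are not independent replicates. Spreads of arrays were compared with exact two-sided permutation tests. Arrays share mice, so these tests treat as separate what is partly shared. With 3 against 3 the smallest two-sided p is 0.1.

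The procedure was tested on simulated data with the measured technical and between-mouse variances. In 10 runs of 15600 probes with 200 of them changed, the test over mice recovered 45.2% of the changes of 1 log2 unit and 87.8% of those of 2 units at an adjusted p under 0.05, with 8.4 false calls per run. In 20 runs with no change, it gave 998 probes at an unadjusted p under 0.05 on average (914 to 1070). The fit with fixed mice gave 106 calls on average at an adjusted p under 0.05 in those runs, because it leaves out the spread between animals. Simulated probes were independent of each other, which real ones need not be.

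Alternatives fixed before the data were examined were the deposited values without centring, arrays scaled to a common median absolute deviation (MAD), each mouse and each array left out, the mouse number as a block, 3 array-level fits, no channel term, robust moderation and weights for mice. Turning the array of WT1 and WT2, turning its channel term, a separate channel term for the 4 KO3 arrays and subtracting plate medians were added after the data were seen, as were all alternatives for the count at an unadjusted p under 0.05, for the named probes, for the fit with fixed mice, for the divisions of the mice and for the pairs of mice. Other sign patterns and exchanges of array labels were also tried before the tests on the array of WT1 and WT2 were chosen. The rule for probes to name asked for named genes. In their absence, the 2 probes on each side with the smallest p and no overlap between genotypes are given, a choice made after their values were seen. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.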

Results

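Aquaporin-1 is the water channel of the thin descending limb of Henle and of the descending vasa recta, and mice that lack it concentrate their urine poorly. The inner medulla is the innermost part of the kidney, in which the loops of Henle and the collecting ducts run. The series compared RNA of this tissue between 3 wild-type (WT1, WT2, WT3) and 3 knockout mice (KO1, KO2, KO3), on 12 two-channel arrays. An array is named here by its channel 1 mouse followed by its channel 2 mouse. All differences are in units of the deposited log ratio, treated as log2.

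The first comparison asked how far mice of 1 genotype differ from each other, which is the background for any effect of the knockout. Log ratios spread less on arrays of 2 WT mice than on arrays of 2 KO mice. On the 3 WT-WT arrays the MAD of the log ratios was 0.369 ± 0.035 (SD, n = 3 arrays), against 0.534 ± 0.093 (n = 3) on the 3 KO-KO arrays, and each KO-KO array was wider than each WT-WT array. The difference of 0.164 gave p = 0.1 in an exact two-sided permutation test, the smallest value that 3 against 3 can give. KO3 was on 2 of the 3 KO-KO arrays, and the array without it, KO1-KO2, had a MAD of 0.432. On the 6 WT-KO arrays the MAD was 0.416 ± 0.051 (n = 6), against 0.451 ± 0.110 (n = 6) on the same-genotype arrays, a difference of -0.035 that lay within the spread between arrays (exact two-sided permutation p = 0.481). The MAD of WT-KO arrays was 0.348, 0.417 and 0.373 with a WT mouse in channel 1. With a KO mouse there it was 0.413 (KO2-WT1), 0.463 (KO3-WT2) and 0.483 (KO3-WT1). All arrays with a WT mouse in channel 1, the WT-WT arrays among them, also come first in the series. The genotype of same-genotype arrays can thus not be told apart from channel 1 genotype or array order. As a standard deviation the values were 0.523 ± 0.085 for WT-WT, 0.740 ± 0.141 for KO-KO and 0.579 ± 0.071 for WT-KO arrays. After the channel term was removed, the MAD was 0.368 ± 0.001 on WT-WT and 0.453 ± 0.052 on KO-KO arrays (exact permutation p = 0.1), while the standard deviations overlapped (exact permutation p = 0.3).

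**Figure D1:**
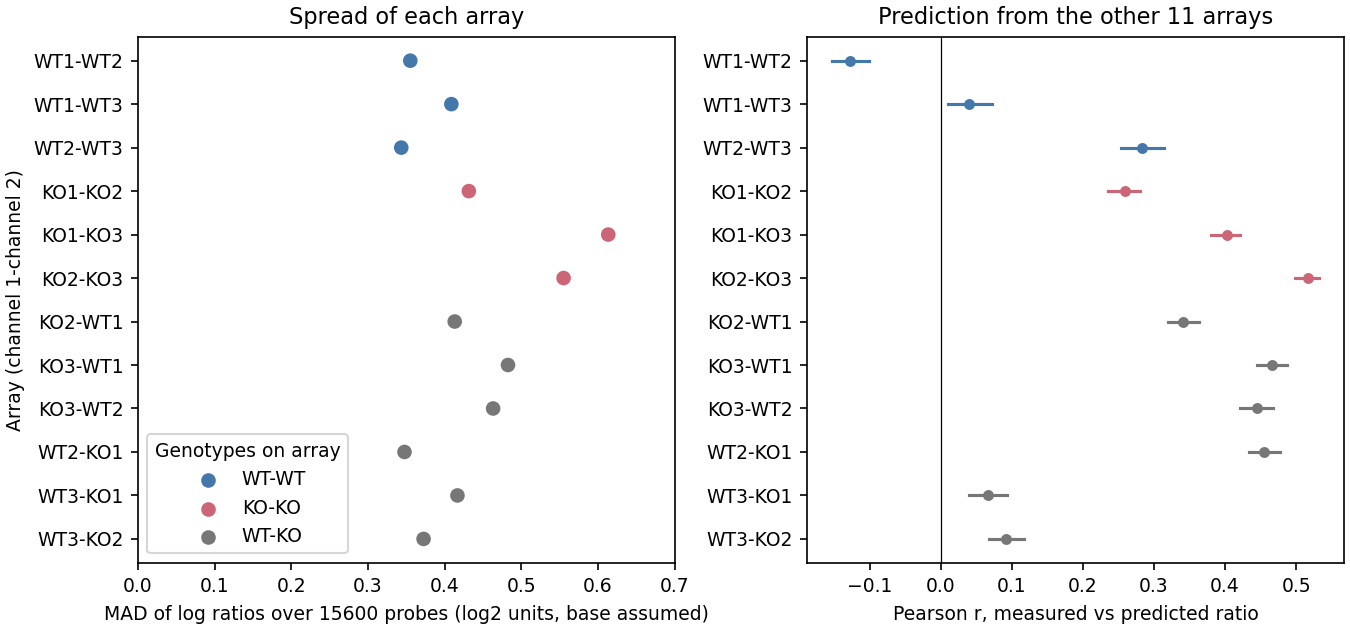
Left, MAD of the log ratios of each array over all probes, in log2 units with the base assumed, with points coloured by the genotypes on the array. Right, Pearson correlation across probes between each array's ratios and those predicted from the other 11 arrays, with bars for the 95% bootstrap interval over source plates. In the left panel the 3 KO-KO arrays have higher values than the 3 WT-WT arrays, and WT1-WT2 is the only array below 0 in the right panel.

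Per probe, the median standard deviation between the 3 mice of a genotype was 0.158 for WT and 0.198 for KO, and 61.1% of probes varied more between the KO than between the WT mice. The median technical standard deviation of a single array ratio was 0.393, which leaves 0.180 for the value of a mouse within its genotype. For the median probe the observed spread between mice was thus of the size of the technical error. The spread between mice rests on fewer degrees of freedom, which lowers its median, so these medians do not show that animals added no spread. Averaged over probes, the variance between mice of 1 genotype was 0.085. The technical variance of a single array ratio averaged 0.270, and a mouse value carries 0.208 of it per unit.

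The loop of arrays also allowed each array to be compared with the others. Predicted ratios combined the mouse values with the channel term. They correlated positively with measured ratios on 11 of the 12 arrays, from r = 0.040 (95% interval 0.010 to 0.072) on WT1-WT3 to r = 0.516 (0.498 to 0.533) on KO2-KO3. The mean over the 12 arrays was 0.270. On WT1-WT2 the correlation was -0.128 (-0.153 to -0.101). This came mainly from the channel term, which alone correlated at -0.250, against -0.014 for the mouse values alone. The mouse values alone also correlated below 0 on WT1-WT3 (-0.170) and WT3-KO1 (-0.100), where the channel term gave 0.432 and 0.395. The correlation therefore does not settle the direction of the ratios on these arrays. The labels as given left a mean residual variance of 0.270, below each of 100 random assignments of the labels and channel orders to the arrays (lowest 0.279). Random assignments change most arrays together, so this does not exclude an error in a few arrays. Of 66 exchanges of labels between pairs of arrays, 5 lowered both the mean and the median residual variance, and the lowest mean was 0.234.

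The second comparison was between individual mice, in the fit to all 12 arrays with the array error as yardstick. KO3 stood apart from all 5 other mice. It differed at an adjusted p under 0.05 in 646 probes from WT1, 655 from WT2, 169 from WT3, 287 from KO1 and 305 from KO2, whereas the other 10 pairs of mice differed in 0 to 70 probes. After plate medians were subtracted, its 5 pairs gave 182 to 570 probes and the other 10 gave 1 to 73. Against KO1 and KO2 together, KO3 differed in 537 probes, 361 on one side and 176 on the other, by a median size of 1.21 among these 537. Over all probes its median absolute difference was 0.244 from KO1 and 0.239 from KO2, against 0.208 between KO1 and KO2. The separation of KO3 was smaller once arrays were scaled to a common MAD, with 29 to 403 probes in its 5 pairs and 1 to 109 in the other 10. With WT1-WT2 turned, the 5 pairs gave 174 to 779 probes and the other 10 gave 0 to 35.

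Over all 15 pairs, WT-KO pairs differed in 180 probes on average, KO-KO pairs in 198 and WT-WT pairs in 1. The KO-KO mean was carried by KO3, since KO1 and KO2 differed from it in 287 and 305 probes and from each other in 1. By the median absolute difference between mice, the genotypes ranked second of the 10 divisions of the 6 mice (exact permutation p = 0.2), and by the standard deviation first (exact permutation p = 0.1). The 3 pairs of mice that never shared an array are all WT-KO pairs and carry more technical error. Their median absolute difference averaged 0.239, against 0.212 for WT-KO pairs on a shared array and 0.207 within genotypes. The pairs of the 5 mice other than KO3 were compared after KO3 had been seen to stand apart. The 6 WT-KO pairs gave 4 to 70 probes (mean 25.5), and the 4 same-genotype pairs gave 0 to 2 (mean 1). WT3 differed from KO1 in 5 probes and from KO2 in 4, and the higher counts lay in pairs with WT1 or WT2. The difference in means of 24.5 was the highest of the 10 ways to divide the 5 mice into 2 and 3 (highest other 21.2; exact one-sided permutation p = 0.1, the smallest possible). With arrays scaled the ranges were 11 to 109 and 1 to 6. With WT1-WT2 turned, WT-KO pairs gave 0 to 35 probes and same-genotype pairs 0 to 2, so the ranges then overlapped, and the difference in means was 9.5, against 6.17 for the highest other division. With a separate channel term for the 4 KO3 arrays the ranges were 0 to 16 and 0 to 1, and the difference in means of 5.08 stood against 4.25. That term also adds to the error. A channel bias shared by these arrays would move KO1 and KO2 by 0.25 per unit, WT1 and WT2 by -0.25 and WT3 by 0. Such a bias could give the higher counts in pairs with WT1 or WT2 without a genotype effect.

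**Figure D2:**
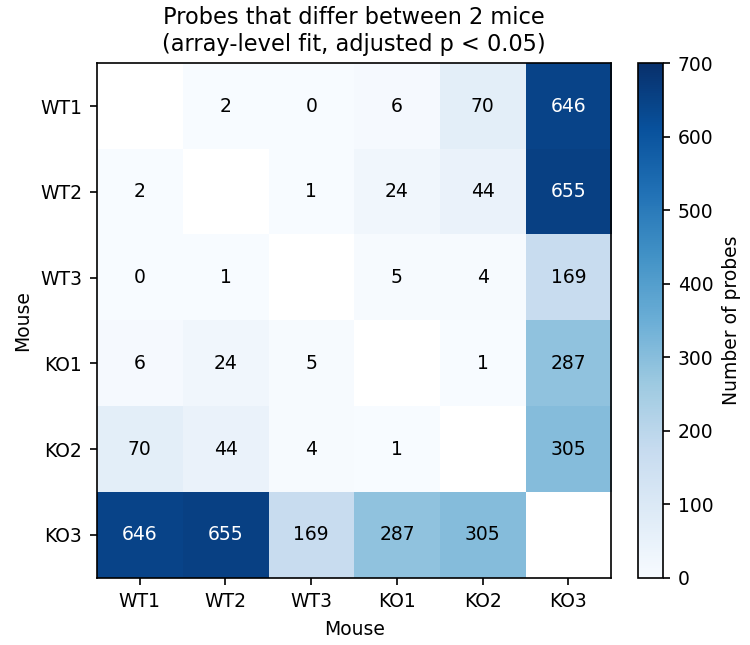
Number of probes that differ between each pair of mice at an adjusted p under 0.05 (limma, 12 arrays, mice as fixed terms). The row and column of KO3 hold 169 to 655 probes, and the other pairs hold 0 to 70.

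The main comparison asked which probes differ between the genotypes when the mouse is the replicate. No probe (0) passed an adjusted p of 0.05 in limma's test over the 6 mice, and the smallest adjusted p was 0.118. At an unadjusted p under 0.05 there were 1529 probes (9.80%), where 5% would be 780, and at an unadjusted p under 0.01 there were 408, where 1% would be 156. The test was liberal in simulated data with no genotype effect, which gave 998 probes on average and at most 1070 at an unadjusted p under 0.05. Simulated probes were independent and had the same between-mouse variance in both genotypes. Real divisions of the mice other than the genotypes gave 267 to 1482, so the simulated range is no bound for these data. Of the 1529, 942 lay on one side of 0 and 587 on the other. Differences were mostly small, with a median size of 0.147 and a 95th percentile of 0.636. They exceeded 1 unit in 240 probes, the largest being 3.57. All 3 KO mice lay beyond all 3 WT mice in 2496 probes (16%), where chance gives 10% for exchangeable values and simulated data of this design with no genotype effect gave 11.3% to 12.1%. It also held for 185 of the 240 probes with a difference over 1. Those were chosen by the same mouse values, so a high share follows from the choice, and no reference was computed for them.

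The call depended on what counted as a replicate. Tested against array error with the mice as fixed terms, 249 probes passed an adjusted p of 0.05 in limma, 203 on one side and 46 on the other, and 214 of them also had an unadjusted p under 0.05 over mice. Simulated data with no genotype effect gave up to 155 such calls in that fit. In the same fit, KO3 alone differed from the WT mice in 949 probes, and KO1 and KO2 together differed in 62. Of the 249, 172 were called for KO3 alone against the WT mice but not for KO1 and KO2 together. With a separate channel term for the 4 KO3 arrays the 249 fell to 80. With any 1 mouse and its 4 arrays left out, which leaves fewer arrays for the error, the 249 fell to between 0 (without WT3) and 40 (without KO1), and to 2 without WT1, 15 without WT2, 22 without KO2 and 4 without KO3. With the 6 WT-KO arrays alone treated as replicates 171 probes passed, and with all 12 arrays treated as replicates 52 did. Without WT2 the count at an unadjusted p under 0.05 fell to 995, without KO3 it was 1476, and with WT1-WT2 turned it was 1597, with 2 probes past an adjusted p of 0.05 in limma.

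Probe H3104D07 had the smallest p. Its KO mice averaged -0.95 ± 0.14 (SD, n = 3) and its WT mice 0.95 ± 0.26 (n = 3), relative to the mean of the 6 mice. The difference of 1.91 in size (SE 0.16, 95% interval -2.30 to -1.52 with channel 1 as numerator) is 3.76-fold if the values are log2 and 6.75-fold if they are natural logarithms, with an adjusted p of 0.118 in limma. All 6 WT-KO arrays showed it in the same direction. This count, and those of the next 3 probes, are no separate support. The estimate is the mean of these arrays, and the probes were chosen by their p. Over 31 alternatives its limma adjusted p ran from 0.00147 to 0.435, and it passed the threshold in 6. The lowest values, 0.00147 to 0.00531, came from the 3 array-level fits, which leave out all or part of the spread between animals. In the test over mice this probe passed, with a limma adjusted p of 0.036, when the array WT2-WT3 was left out. It also passed there with 0.048 without WT3-KO2 and with 0.039 when WT1-WT2 was turned. On the same side, H3020E01 differed by 2.27 in size (SE 0.27; KO mice -1.14 ± 0.38, WT mice 1.14 ± 0.43, n = 3 each), again in 6 of 6 arrays. On the opposite side, H3142D06 differed by 1.23 (SE 0.14; KO mice 0.61 ± 0.18, WT mice -0.61 ± 0.08) in 5 of 6 arrays, and H3076E06 by 1.44 (SE 0.18; KO mice 0.72 ± 0.34, WT mice -0.72 ± 0.10) in 6 of 6 arrays. For H3142D06 the array in the other direction was KO3-WT2 (-0.08), where the fitted values were 0.65 for KO3 and -0.69 for WT2. For H3076E06 the 2 arrays with KO3 gave 0.13 and 0.20 and the other 4 gave 1.41 to 2.41. Without KO3 the difference was 2.23. Its fitted values were 0.36 for KO3, -0.74 for WT1 and -0.80 for WT2. In both probes KO3 thus lay further from WT1 and WT2 in the fit than on its arrays with them. Those array ratios still hold the channel term. H3020E01, H3142D06 and H3076E06 each had a limma adjusted p of 0.199. Among the alternatives they passed the threshold only in array-level fits.

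**Figure D3:**
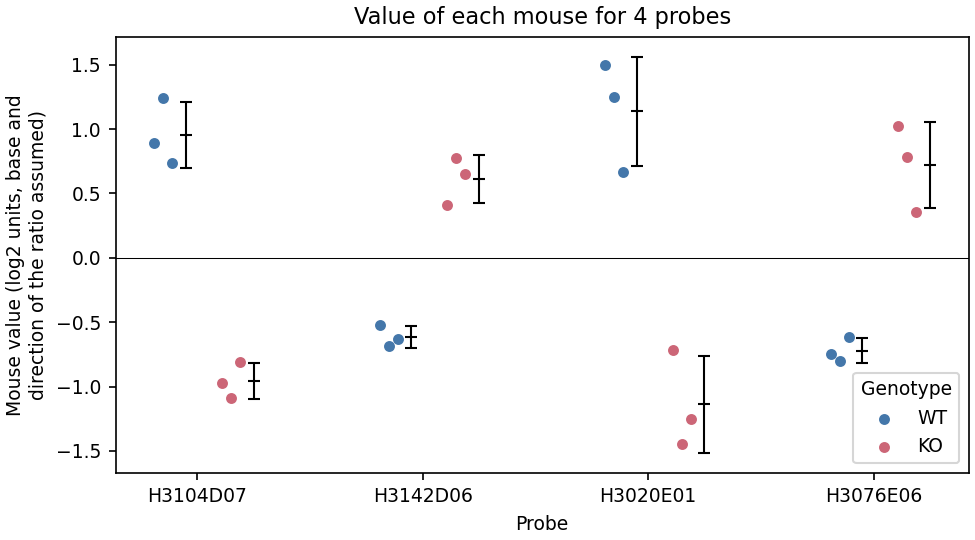
Value of each mouse, in log2 units relative to the mean of the 6 mice and with the base and the direction of the ratio assumed. Shown are the 2 probes on each side with the smallest p among those without overlap between genotypes. Points are mice, and bars give the mean ± SD of the 3 mice of a genotype. The genotypes do not overlap in the 4 probes because the probes were chosen so, and the differences are 1.23 to 2.27 in size.

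The genotype division was also set against every other way to divide the 6 mice into 3 and 3. It gave the highest count of the 10 divisions at an unadjusted p under 0.05 (limma), 1529 probes, but WT1, WT2 and KO1 against WT3, KO2 and KO3 gave 1482. The remaining 8 divisions gave 267 to 1178 probes. The divisions were rerun only with changes to WT1-WT2, and the first place of the genotypes was lost when that array was left out. With that array turned the genotypes gave 1597 probes and the highest other division 1403, and with its channel term turned 1469 and 1426. With the array left out they gave 1259, below the 1265 of WT1, WT3 and KO2 against WT2, KO1 and KO3. With all 12 arrays as deposited in direction and without the KO3 channel term, no division gave a probe at an adjusted p under 0.05 in limma (0 in each of the 10).

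**Figure D4:**
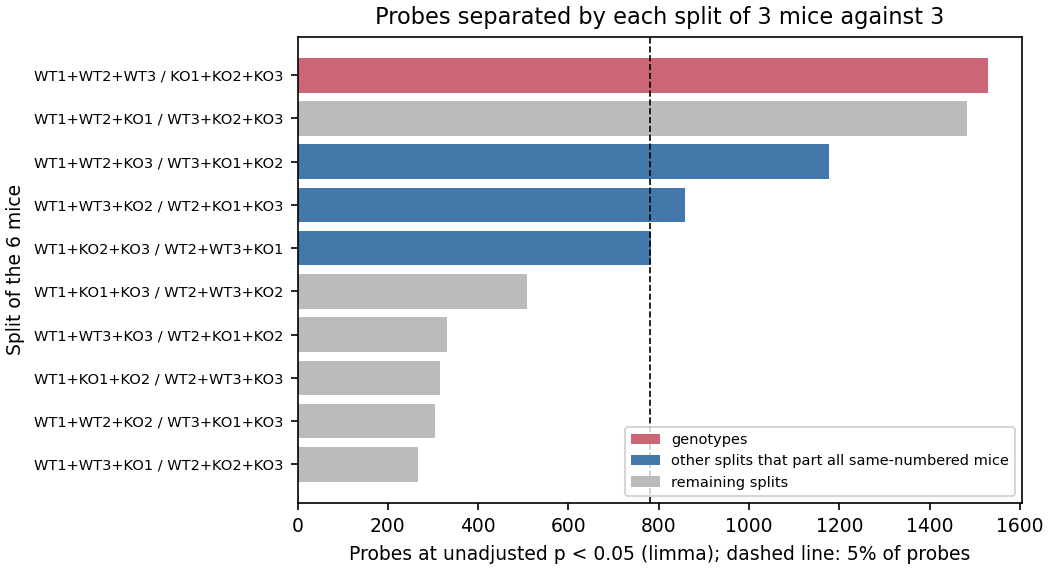
Number of probes at an unadjusted p under 0.05 (limma, 6 mouse values) for each of the 10 divisions of the 6 mice into 3 and 3. The dashed line marks 5% of the probes (780), and colours mark the genotypes, the other divisions that separate all mice of the same number, and the rest. The genotypes give 1529 probes and the next division 1482.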

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

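The turned array, the separate channel term for the KO3 arrays, the turned channel term, the plate medians and every alternative for unadjusted counts, named probes, pairs with KO3 and the fit with fixed mice were chosen after the data were seen. The count of 0 probes past an adjusted p of 0.05 held for uncentred values, scaled arrays, the replicate block by mouse number, no channel term, robust moderation, weights for mice, plate medians subtracted, the turned channel term, the separate KO3 channel term and a threshold of 0.1, and it was 0 without each of the 6 mice. Leaving out each array gave 0 to 2, and turning WT1-WT2 gave 2. It was 249 with the mice as fixed terms, 52 with 12 arrays and 171 with 6 arrays as replicates, and 408 at an unadjusted p under 0.01. The 249 became 0 to 40 without a mouse and its arrays, which leaves fewer arrays for the error, and 232 to 304 with uncentred, scaled, plate-subtracted or turned values, and 80 with the KO3 channel term, which adds to the error of the difference. The 3 array-level fits leave out all or part of the spread between animals. At an unadjusted p under 0.05 the 1529 probes became 995 to 1672 without a mouse, 1181 to 1874 without an array and 1284 to 2090 under the others, and the channel term could not move it because the loop is balanced. The labels do not say that the numbers pair the mice, and the deviations of same-numbered mice (r = -0.08, -0.24 and -0.04) do not decide it, because array error alone gives r = -0.2 in this loop. The replicate block gave 0 and, unadjusted, 1284 probes. The 4 named probes passed the threshold in 14 of 124 alternative values, in many of which the estimate itself could not move. The lowest count among the 5 pairs with KO3, 169, fell to 29 with scaled arrays and to 75 with the KO3 channel term, and the cause was not tested. With uncentred values and scaled arrays, the only alternatives run for them, the technical standard deviation of 0.393 became 0.395 and 0.383, that between mice of 0.198 stayed at 0.198 and became 0.189, and the mean correlation of 0.270 stayed at 0.270 and became 0.264. No values were missing, so filters on missing values change nothing. Filters on dim spots, Aqp1 and gene list alternatives were not run for want of intensities and gene names.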

Other observations

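All tests in this part were chosen after the patterns they concern had been seen, and for the tests of plate offsets and of channel bias alone the bounds were written before their values were computed. The rank correlation, the design shifts, the pair counts with a KO3 channel term and the simulation given beside the tests of channel bias were added after those values.

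The 336 probes with the Z3 prefix had higher ratios on the 4 arrays that carry KO3. Their median log ratio was 0.189 to 0.403 on these 4 arrays and -0.040 to 0.117 on the other 8, with the same sign whichever channel held KO3, so that the KO3 value itself had a median of -0.044 over them. Over these probes the median of a separate channel term for the 4 arrays was 0.31, and the median KO-WT difference was 0.08 without that term and -0.01 with it.

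The excess of probes at an unadjusted p under 0.05 for the genotypes (1529 against 780) was weighed against 4 explanations. Of the 10 divisions of the mice, 1 gave as many probes, the genotypes themselves, and the highest other gave 1482, and 10 divisions are too few for a share under 0.05. Offsets shared by a source plate are argued against, since the count was 1573 after plate medians were subtracted. Divisions that separate all same-numbered mice carry more technical error, and this stays open, since the 3 others of this kind gave 1178, 858 and 782 but, without the array WT1-WT2, WT1, WT3 and KO2 against the rest gave 1265 against 1259 for the genotypes. A channel bias on the 4 KO3 arrays would shift the KO-WT difference by 0.333 per unit and stays open, since with a separate channel term for them the count was 1755, above the 1254 to 1441 of simulated data with no effect and independent probes, but the bound set beforehand lay below even those, and another division gave 1650 in the same fit.

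The separation of KO3 could come from the animal or from its 4 arrays. Noise is argued against, since the mean residual standard deviation of these arrays was 0.363, against 0.366 ± 0.048 (SD, n = 8) for the others, and so are plate offsets, since the lowest of its 5 pairs had a count of 182 after plate medians were subtracted, against at most 73 in the other 10 pairs. A channel bias shared by the 4 arrays is argued against as the whole cause. Per unit it shifts KO3 and WT3 by 0, KO1 and KO2 by 0.25 and WT1 and WT2 by -0.25. It would thus not part KO3 from WT3. With a separate channel term the 5 pairs gave 75 to 497 probes and the other 10 gave 0 to 16. A part played by the bias stays open, since it would move KO1, KO2, WT1 and WT2 against KO3. With the term, which also adds to the error, KO1-KO3 fell from 287 to 75 probes. WT3-KO3, which the bias does not move, fell from 169 to 109. The test set beforehand met its bound against this bias only narrowly. The KO3 levels from channel 1 and channel 2 correlated at r = 0.034 (95% interval over plates 0.003 to 0.068), with Spearman's rho at -0.065. In the other mice r ran from -0.391 (KO1) to 0.206 (WT2). With the channel term removed, r was 0.061 for KO3 and ran from -0.395 (KO1) to -0.115 (WT2) in the other mice. In those mice the levels from the 2 channels thus ran against each other, which is a limit of all mouse values. A stretch of all ratios on these arrays stays open, because with arrays scaled the lowest of the 5 pairs fell to 29 and 2 of the 5 lay above the highest other pair, as does a difference between individual animals, which was not tested.

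The array WT1-WT2 ran against its prediction (r = -0.128), through the channel term (-0.250) more than through the mouse values (-0.014). If its ratio were turned as a whole, the mean residual variance would fall from 0.270 to 0.255 but the median would rise from 0.155 to 0.158, which leaves this open. If its channel bias alone were turned, as when the dyes of this array were exchanged without exchanging the ratio, the correlation would be 0.155 (0.122 to 0.189), and mean and median residual variance would fall to 0.247 and 0.150, which is consistent with that explanation, although turning the channel term lowered both variances for 2 of the 12 arrays, this array and KO2-WT1. Exchanged labels are possible too, since of 66 exchanges tried, 2 of the 11 with this array lowered both variances, but so did 3 of the 55 exchanges among the other arrays, the lowest being WT1-WT3 with WT3-KO2 (mean 0.234). With the labels as given, the KO-WT estimates do not depend on this array's ratios, and it enters the tests through the error. Its exchange with WT3-KO1 was among those that lowered both variances, and under it these ratios would enter the estimates. The estimates would also change under the exchanges of WT1-WT3 with WT3-KO2 and of WT3-KO1 with WT2-WT3, which lowered both variances too. The KO-WT test was not rerun with exchanged labels.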
